A study of Mus musculus with 18 samples.

How the data were processed

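Total RNA of mouse embryonic stem cells was hybridised to Affymetrix mouse expression arrays, 1 biotin-labelled sample per array, with 3 biological replicates in each of 6 groups. Per the labels' protocols, CGR8 cells were grown in GMEM with 10% serum and LIF, transfected with plasmids by lipofection, and their RNA was extracted with Trizol. The groups were the empty vector, Foxd3, CA-NFATc3, Foxd3 with CA-NFATc3, and Foxd3 conditional knockout cells (Foxd3fl/fl:Cre-ERT) with tamoxifen for 0 days (DMSO) or 2 days; the labels give the knockout cells the same source name and protocols. The use of feeder cells, the plasmids' sequences, the time after transfection and the days of hybridisation are not given in the sources used here.

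The deposited values are an intensity for each probe set, the MAS5 signal on a linear scale, per the submitters' processing notes, which name MAS5 without a version. The authors' scaling was read from the values: the mean signal without the lowest and highest 2% was 500 in every array, as MAS5 scaling to a target of 500 gives. All values were above 0. Median signals were 55.2 to 67.1 in the transfected cells and 73.0 to 80.7 in the knockout cells. The background subtraction and detection calls behind each signal remain unknown, since only the signals were deposited. At most 0.00443% of the values were identical between any pair of arrays, and all 18 columns were matched to a labelled sample.

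Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol in the platform's annotation, 932 had several symbols and 9160 had none. Entrez gene numbers of 34741 were found in the gene table of assembly GRCm38.p6, and 0 symbols needed updating. The probe sets with 1 symbol covered 18193 genes, 9010 of them with more than 1 probe set; each gene was represented by the probe set with the highest mean log2 value over all arrays. Signals were used as deposited, increased by 32 and put on the log2 scale. Genes were tested if the median of all deposited values, 65.8, was reached in at least 3 arrays of the fit, which left 11609 genes in the 12 arrays of transfected cells and 12093 in the 6 arrays of knockout cells.

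Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a variance trend), separately for the transfected and the knockout cells, without covariates. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The contrasts were Foxd3, CA-NFATc3 and both against vector, both against CA-NFATc3, both against Foxd3, the interaction (both minus CA-NFATc3, minus the difference of Foxd3 and vector) and tamoxifen against DMSO. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

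The 17 gene lists were naive and core pluripotency, primed epiblast, primitive streak and mesendoderm, primitive and visceral endoderm, trophectoderm, neuroectoderm, neural crest, mesoderm and smooth muscle, calcineurin-NFAT components and targets, immediate early and AP-1, p53 targets, interferon response, fibroblasts (feeder cells), cell cycle, cholesterol synthesis, integrated stress and unfolded protein response, and genes of the 2-cell stage and germline. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and with fry beside it. With an estimated correlation the called lists were 3 for Foxd3 against vector, 2 for both against vector, 1 for both against Foxd3, 1 for tamoxifen against DMSO and 0 in the other contrasts. The directional test of fry asks only whether a list's genes move, on balance, one way, and its results are not given below. A list's median, mean and test differed in sign in 13 of 119 results, 0 of them called by camera.

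Named genes followed a rule. For each contrast of 2 groups these were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, and the 3 called members with the largest change in each called list. For the interaction they were the 5 largest positive and 5 largest negative terms. Foxd3, Nfatc3, Nfatc1, Nfatc2, Nfatc4, Rcan1, Src, Pou5f1, Nanog, Sox2, Cdx2, Gata6, T and Fgf5 were always included; genes outside the rule are said to be chosen after their values were seen. Src and the other Nfatc genes passed in no contrast, except Nfatc4 with tamoxifen. T and some other genes of the lists are not analysed here. The groups, contrasts, lists, naming rule and alternative settings were set before the data were examined.

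Whether the replicate numbers pair the samples was checked by correlating residuals from the group means across genes. In the transfected cells all 18 pairs of arrays with the same number correlated at 0.104 to 0.315 (median 0.156), and the 36 pairs with different numbers at -0.282 to 0.0133. This is a hint from the data that equal numbers share something, so counts with the replicate number as a block are given beside those without. In the knockout cells the 3 pairs lay between -0.0425 and 0.0152. Changes that share no array were compared across genes by Pearson's r and Spearman's rho, with a jackknife over arrays; for contrasts that share arrays, 100 simulated data sets without any effect gave the correlation due to the shared arrays.

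The alternatives were no offset (values under 1 set to 1) and an offset of 100; quantile normalization and centring each array on its median; no filter and a filter on the mean; all probe sets and the mean of the probe sets of a gene; no variance trend, all 18 arrays in 1 fit, and only the 2 groups compared; array weights; the replicate block; a threshold of at least 2-fold; leaving out each replicate in turn; an estimated inter-gene correlation; and Spearman's rho or only the genes called in either contrast for the correlations. The pipeline was tested on simulated data with 200 changed genes. For the design of Foxd3 against vector it recovered 53.7, 92.5 and 100% of genes changed by 0.5, 1 and 2 on the log2 scale. There were 12 false calls (6.82% of calls). For tamoxifen against DMSO it recovered 71.6, 94.0 and 100%, with 15 false calls (7.81%). Both shares lay above the adjusted p threshold of 0.05. Noise here and in the simulated data sets above was drawn independently for each array. It lacked the correlation of residuals seen between transfected arrays of equal replicate number.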

Results

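Transcript levels of mouse embryonic stem cells were measured on 18 oligonucleotide arrays, 1 labelled sample per array, in 6 groups of 3 biological replicates. In 12 arrays, cells of the CGR8 line had been transfected with an empty vector, Foxd3, CA-NFATc3 or both plasmids. Foxd3 is a forkhead transcription factor expressed in pluripotent cells and in the neural crest. CA-NFATc3 is, by the usual meaning of the name, a constitutively active form of NFATc3, a transcription factor activated by calcineurin. The other 6 arrays were of Foxd3 conditional knockout cells, given DMSO (0 days of tamoxifen) or tamoxifen for 2 days, which activates a Cre recombinase that deletes Foxd3. The median signal per array lay between 55.2 and 67.1 in the transfected cells and between 73.0 and 80.7 in the knockout cells, and replicates of a group correlated at r between 0.986 and 0.991 across probe sets. The number of arrays limits the precision. Changes are given below as log2 differences ± SE of the limma fit with 3 arrays per group, and folds are of the signal plus 32. Where a group mean lay under 65.8, the signal needed for testing, the size of a log2 change and its order among others depend on that offset. A fold is then given as "at least" the mean of the brighter group over that of the dimmer one with its lower arrays set to 65.8. For each called gene named in a comparison of 2 groups, all 3 arrays of one group lay above all 3 of the other.

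The Foxd3 transcript, read by 1 probe set, was lower in the arrays labelled as overexpressing Foxd3. Its signal was 443 ± 55.9 (SD, n = 3) with the vector, 237 ± 5.95 in the arrays labelled Foxd3, 451 ± 38.6 with CA-NFATc3 and 234 ± 37.7 in the arrays labelled with both. This is a log2 change of -0.81 ± 0.13 for Foxd3 against vector (limma adjusted p = 0.00169) and -0.87 ± 0.13 for both against CA-NFATc3 (adjusted p = 0.000452). The direction is opposite to the label, and a probe set lying outside the inserted sequence would not read the plasmid; where it lies on the transcript is not given in the sources used here. The samples are therefore named by their labels throughout. In the conditional knockout cells the signal was 219 ± 25.9 with DMSO and 31.4 ± 29.6 with tamoxifen, the direction of the label. Nfatc3 was read by a pair of probe sets, and neither passed the test for CA-NFATc3 against vector. The stronger one went from 1581 to 1732 (log2 change 0.13, adjusted p = 0.352), the weaker one from 253 to 325 (0.33 ± 0.15, adjusted p = 0.318). The level of the CA-NFATc3 plasmid was thus not visible in either Nfatc3 probe set.

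**Figure D1:**
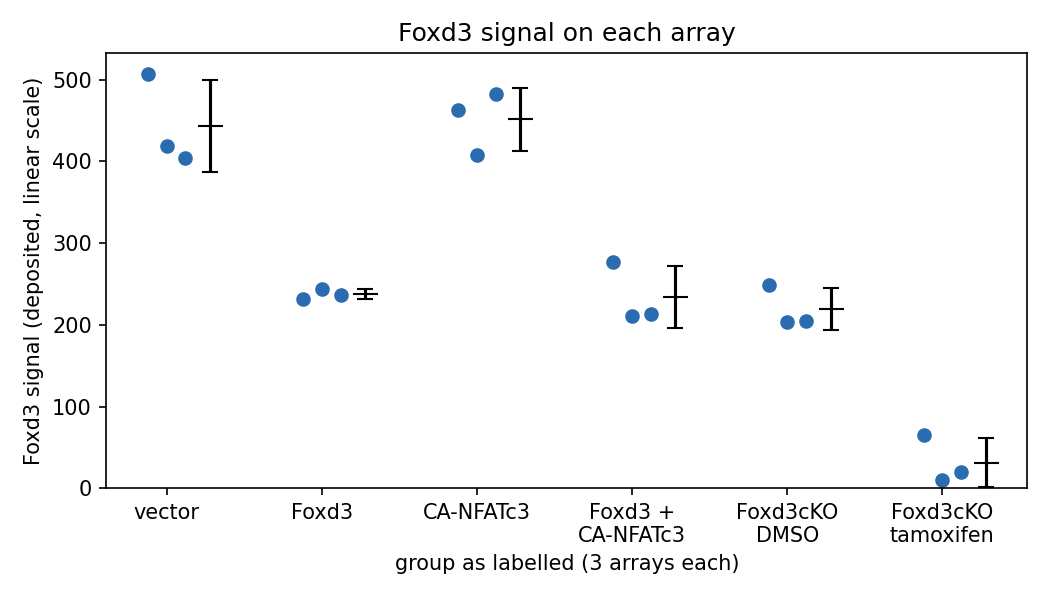
Deposited signal of the Foxd3 probe set on a linear axis in each of the 18 arrays by labelled group, with 1 point per array and the mean and SD beside them. The 3 arrays labelled Foxd3 lie between 232 and 244, below the 3 vector arrays at 404 to 507, and the tamoxifen arrays lie lowest.

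The arrays labelled Foxd3 were compared with the vector arrays for the effect of Foxd3 overexpression on the stem cells; since the Foxd3 signal went against the label, the directions below hold for the labels only. Genes of the primed epiblast (the later, post-implantation-like state) and of neuroectoderm rose, and genes of the naive and core pluripotency list fell. The largest rises were in Hs6st2, a heparan sulphate 6-O-sulphotransferase, from a signal of 59.6 to 928 (at least 13.8-fold, log2 3.38 ± 0.15, adjusted p = 3.72e-09), and in Efnb2, the membrane ligand ephrin-B2 (8.93-fold, log2 3.16 ± 0.21, adjusted p = 7.03e-07). Cdkn1c, the cyclin-dependent kinase inhibitor p57, rose 4.85-fold (log2 2.28 ± 0.18, adjusted p = 2.63e-06). Ms4a4d (log2 2.54), Pkdcc (2.21), Pdzph1 (2.02), Cnr1, a cannabinoid receptor (1.98, and 0.14 in its other probe set), and Cyp1b1, a cytochrome P450 (1.92), also rose. Falls were smaller, with Tex14, a protein of germ cell bridges, at -0.77 ± 0.13 (adjusted p = 0.00299). Of the genes with the 8 largest falls, Zap70 (-1.13), Lrcol1, Rab25, Serpinb6c, Reps2 and Myof lost their call without at least 1 of vector replicates 1 to 3 or Foxd3 replicates 1 to 3, with adjusted p between 0.0571 and 0.173.

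Of the 11 primed epiblast genes tested, 6 were higher, 0 lower and 5 did not pass (7 higher when adjusted over the list alone). The list median was 0.79 (camera adjusted p = 3.09e-10, and 0.0407 with an estimated correlation). Those higher included Sall2 (1.41 ± 0.19), Pou3f1, the POU factor Oct6 (1.24 ± 0.22), and the de novo DNA methyltransferase Dnmt3b (1.20 ± 0.16). Among the 25 pluripotency genes, 8 were lower, 1 higher and 16 did not pass (9 lower and 1 higher adjusted over the list alone). Their median was -0.21 (adjusted p = 8.95e-10, and 0.0407 with an estimated correlation). Tbx3 (-0.75 ± 0.08, adjusted p = 2.96e-05) and Fbxo15 (-0.59 ± 0.08, adjusted p = 0.000609) fell most. The 1 gene that rose was Lin28a (0.50), chosen here after its value was seen, an RNA-binding protein that blocks let-7 maturation. Pou5f1 (0.01, adjusted p = 0.982), Nanog (-0.15, adjusted p = 0.485) and Sox2 (-0.11, adjusted p = 0.464) did not pass. In neuroectoderm, 2 of 11 genes were higher, 0 lower and 9 did not pass (5 higher adjusted over the list alone). This list had a median of 0.39 (adjusted p = 6.33e-05, and 0.0295 with an estimated correlation). The 2 genes were Sox11 (1.09 ± 0.08, adjusted p = 1.75e-06) and Msi1 (0.52 ± 0.13, adjusted p = 0.0398). Msi1 lost its call without vector replicate 1 or 3 or without any 1 of the Foxd3 replicates (adjusted p 0.0946 to 0.165).

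In limma, 334 of 11609 genes differed between the arrays labelled Foxd3 and the vector arrays, 198 higher and 136 lower, and 66 of them by at least 2-fold (65 higher, 1 lower). With the replicate number as a block the count was 783 (401 higher, 382 lower). It was 187 without vector replicate 3, 158 without Foxd3 replicate 3 and 552 with array weights. The fibroblast list did not pass (median 0.15, adjusted p = 0.279), nor did the calcineurin-NFAT list (median -0.10, adjusted p = 0.788), with Rcan1 at -0.19 (adjusted p = 0.483).

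CA-NFATc3 was compared with vector for the effect of active NFATc3 on the stem cells. Higher genes included 7 of trophectoderm, 4 of primitive and visceral endoderm, 6 immediate early genes and the NFAT target Rcan1 (a feedback inhibitor of calcineurin), and 4 pluripotency genes were lower. S100g, the calcium-binding protein calbindin-D9k, went from a signal of 1.55 ± 0.0409 to 4063 ± 904 (at least 61.8-fold, log2 6.91 ± 0.19, adjusted p = 4.44e-12). Gsn, the actin-severing protein gelsolin, rose 28.3-fold (log2 4.82 ± 0.19, adjusted p = 4.87e-10), Cav1, the main protein of caveolae, at least 14.4-fold (3.95 ± 0.22) and Cyp26a1, which degrades retinoic acid, at least 7.34-fold (3.64 ± 0.24). Dmkn (4.29) and AU015836 (3.97) were also among the largest rises. Rcan1 rose by 1.59 ± 0.11 (adjusted p = 2.05e-07), from a signal of 1196 ± 60.6 to 3702 ± 776. The largest falls were in Myo1f, an unconventional myosin (-1.45 ± 0.18, adjusted p = 0.000112), and Stra8, a gene of meiotic entry (-1.37 ± 0.18, adjusted p = 0.000114). Also among the largest falls were Zap70 (-1.37, not called with the mean of its probe sets, adjusted p = 0.0554), Prmt8 (-1.02), Gfra1 (-0.97), Napsa (-0.95) and Inhbb (-0.92). In its other probe set Inhbb was at -0.26 (adjusted p = 0.646).

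In the trophectoderm list, 7 of 16 genes were higher with CA-NFATc3, 0 lower and 9 did not pass (7 higher adjusted over the list alone). The median was 0.48 (camera adjusted p = 5.61e-07, and 0.0995 with an estimated correlation). Among the 7 were Cited1 (3.16 ± 0.32), the keratin Krt19 (2.29 ± 0.26) and the trophoblast factor Elf5 (2.06 ± 0.25, lost without the offset of 32, adjusted p = 0.0601). In the endoderm list, 4 of 13 were higher, 0 lower and 9 did not pass (5 higher and 1 lower adjusted over the list alone), for a median of 0.45 (adjusted p = 1.21e-06, and 0.104 with an estimated correlation). The highest were the basement membrane collagens Col4a1 (2.97 ± 0.13) and Col4a2 (2.23 ± 0.17) and the endoderm factor Sox17 (1.47 ± 0.25). Beside these, the fibroblast list also passed: 1 of 7 genes, Col3a1 (2.32 ± 0.22), was higher, 0 lower and 6 did not pass (3 adjusted over the list alone). Its median was 0.55 (adjusted p = 0.00918, and 0.0995 with an estimated correlation). That call ended with no filter (adjusted p = 0.263), a filter on the mean (0.187) or all 18 arrays in 1 fit (0.223). The ratio of the 3' to the 5' actin probe sets, a sign of RNA quality, was 2.23 ± 0.0255 with CA-NFATc3 and 2.31 ± 0.0340 with vector. For Gapdh this ratio was 0.908 ± 0.0162 and 0.920 ± 0.0392. Gata6, a master factor of primitive endoderm, was at 0.53 (adjusted p = 0.235), and Cdx2 and Fgf5 lay under the signal filter in the transfected cells.

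Among immediate early genes, 6 of 15 were higher with CA-NFATc3, 0 lower and 9 did not pass (8 higher adjusted over the list alone). Their median was 0.57 (adjusted p = 0.000458, and 0.104 with an estimated correlation). Ccn1, a matricellular growth regulator, rose most (2.77 ± 0.20, adjusted p = 3.09e-07). Of the calcineurin-NFAT genes 4 of 17 were higher, 0 lower and 13 did not pass (4 adjusted over the list alone), for a median of 0.13 (adjusted p = 0.00918, and 0.224 with an estimated correlation). The 4 were Ptgs2, the inducible cyclooxygenase (3.33 ± 0.30), Egr2 (1.82 ± 0.30), Rcan1 and, chosen after its value was seen, Nr4a1 (0.46). The call of this list ended without CA-NFATc3 replicate 2 (adjusted p = 0.0779) or 3 (0.0903). In the pluripotency list 4 of 25 genes were lower, 0 higher and 21 did not pass (4 adjusted over the list alone), with a median of -0.13 (adjusted p = 6.55e-07, and 0.0995 with an estimated correlation). These 4 were Prdm14 (-0.52 ± 0.08), Nr0b1 (-0.51 ± 0.07), Dppa2 (-0.50 ± 0.07) and, also chosen after its value was seen, Klf2 (-0.37). Pou5f1 (-0.15, adjusted p = 0.374), Nanog (-0.16, adjusted p = 0.433) and Sox2 (-0.07, adjusted p = 0.667) did not pass.

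Beside the fibroblast list's median of 0.55, the neural crest list (median 0.67, adjusted p = 0.0301, and 0.104 with an estimated correlation) held 1 called gene of 5, the mesenchymal factor Twist1 (1.68 ± 0.27), with 4 that did not pass (3 higher adjusted over the list alone). Its call ended with the replicate block (adjusted p = 0.0598), with no filter (0.15), a filter on the mean (0.464) or array weights (0.0553), and without vector replicate 2 (0.101) or CA-NFATc3 replicate 1 (0.0732). The cholesterol synthesis list passed (median 0.15, adjusted p = 0.0059, and 0.417 with an estimated correlation) with 0 of 15 genes called by limma (5 at an unadjusted p under 0.05, 3 higher adjusted over the list alone), and it lost its call without vector replicate 2 (0.0504) or CA-NFATc3 replicate 1 (0.0532). Over all genes, 680 differed between CA-NFATc3 and vector, 536 higher and 144 lower, 213 of them by at least 2-fold (208 higher, 5 lower). The replicate block gave 1104 (779 higher, 325 lower), and leaving out CA-NFATc3 replicate 3 gave 349.

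**Figure D2:**
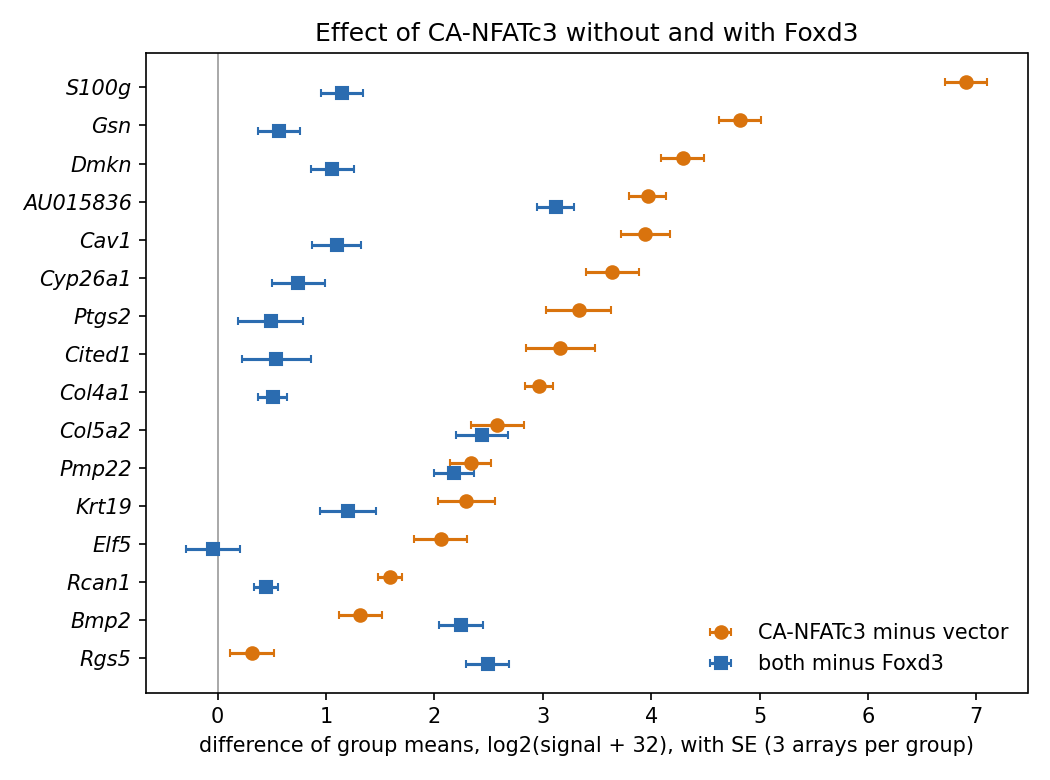
Log2 difference, with SE, for CA-NFATc3 minus vector (circles) and both minus Foxd3 (squares) of 16 genes, 3 arrays per group. S100g lies at 6.91 and 1.15, Rcan1 at 1.59 and 0.45 and AU015836 at 3.97 and 3.12, while Rgs5 lies at 0.32 and 2.49.

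Both plasmids together were compared with vector for their joint effect. As with the label Foxd3, 6 primed epiblast genes were higher and pluripotency genes fell. Pluripotency genes had also fallen as a list with CA-NFATc3 alone. The primed epiblast list did not pass there (median -0.11, mean 0.10, camera adjusted p = 0.597), with 2 of 11 genes called. Pou3f1 (1.19) and, outside that list, Efnb2 (2.10), both chosen after their values were seen, rose with CA-NFATc3 alone. The trophectoderm list did not pass (1 of 16 higher, 1 lower, 14 not passing; 4 and 1 adjusted over the list alone; median 0.02, adjusted p = 0.714). Nor did endoderm, whose mean was 0.25 and median -0.04 (adjusted p = 0.0722, direction up), although 4 of 13 genes were higher, 0 lower and 9 did not pass (4 adjusted over the list alone), Col4a1 (1.21 ± 0.13) and Col4a2 (0.93 ± 0.17) among them. Hs6st2 (3.29 ± 0.15, adjusted p = 5.59e-09) and Efnb2 (2.67 ± 0.21) were again among the largest rises, joined by Bmp2, a bone morphogenetic protein (2.72 ± 0.20, adjusted p = 1.69e-06), and the fibrillar collagens Col5a2 (2.68 ± 0.24) and Col1a2 (2.63 ± 0.26). Rcan1 did not pass (0.26, adjusted p = 0.224). Among falls that kept their call without any 1 array were Mylpf (-0.96 ± 0.11, adjusted p = 5.09e-05), Calcoco2 (-0.99), Inhbb, a subunit of activin B (-0.89), and 2210409E12Rik (-0.88). The other probe set of Inhbb was at -0.26 (adjusted p = 0.586). Nfatc3 (0.20, adjusted p = 0.101) and Nanog (-0.29, adjusted p = 0.0798) did not pass. Nfatc3 did with the replicate block (adjusted p = 0.0311) or all 18 arrays in 1 fit (0.0489). Nanog did with the block (0.0385), quantile normalization (0.0336), all 18 arrays in 1 fit (0.0325), only the 2 groups in the fit (0.0194) or array weights (0.0266).

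Of the 25 pluripotency genes, 9 were lower with both plasmids than with vector, 1 higher and 15 did not pass (14 lower and 1 higher adjusted over the list alone). The list's median was -0.26 (adjusted p = 4.53e-12, and 0.0263 with an estimated correlation). Tbx3 (-0.74 ± 0.08), Fbxo15 (-0.67 ± 0.08) and Tfcp2l1 (-0.57 ± 0.09) fell most, and the 1 that rose was again Lin28a (0.44). In the primed epiblast list 6 of 11 were higher, 0 lower and 5 did not pass (6 higher adjusted over the list alone), and the median was 0.73 (adjusted p = 5.53e-07, and 0.0937 with an estimated correlation). Sall2 (1.37 ± 0.19) and Pou3f1 (1.24 ± 0.22) led it. The fibroblast list passed beside them, with 3 of 7 higher, 0 lower and 4 that did not pass (4 higher adjusted over the list alone). Its median was 0.51 (adjusted p = 0.000282, and 0.0263 with an estimated correlation), and the 3 genes were Col1a2, Col3a1 (1.63 ± 0.22) and the gelatinase Mmp2 (0.53 ± 0.14). Mmp2 lost its call without vector replicate 1, 2 or 3 or without replicate 1 or 3 with both (adjusted p 0.0513 to 0.15).

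With both plasmids, neuroectoderm genes rose as a list, with 2 of 11 higher, 0 lower and 9 that did not pass (4 higher and 2 lower adjusted over the list alone). The median was 0.27 (adjusted p = 0.0284, and 0.0937 with an estimated correlation), and Sox11 was at 0.91 ± 0.08. Of the immediate early genes, 5 of 15 were higher, 1 lower and 9 did not pass (5 and 2 adjusted over the list alone), with a median of 0.19 (adjusted p = 0.0199, and 0.283 with an estimated correlation). Ccn1 (1.83 ± 0.20) and Ccn2 (1.46 ± 0.28) rose most. Mesoderm and smooth muscle genes also rose as a list, beside the fibroblast list's median of 0.51, with 4 of 10 higher, 1 lower and 5 that did not pass (5 and 1 adjusted over the list alone), among them the tropomyosins Tpm1 (0.76 ± 0.13) and Tpm2 (0.54 ± 0.09). Here the median was 0.45 (adjusted p = 0.0284, and 0.0937 with an estimated correlation). Without replicate 1 of the arrays with both, the calls of neuroectoderm (adjusted p = 0.124) and mesoderm (0.0685, and 0.087 with a filter on the mean) ended, and without replicate 3 that of the immediate early genes (0.074). Limma called 559 genes, 404 higher and 155 lower, 119 of them by at least 2-fold (117 higher, 2 lower). The count was 1122 with the replicate block (700 higher, 422 lower), 322 without vector replicate 3, and 347 and 333 without replicates 2 and 3 with both.

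Both plasmids were then set against CA-NFATc3 alone, which shows what the label Foxd3 adds where NFATc3 is active; here too the Foxd3 signal went against the label. Genes that CA-NFATc3 had raised were lower with both: S100g (-5.60 ± 0.19, adjusted p = 1.07e-10), Gsn (-4.17 ± 0.19, adjusted p = 4.21e-09), the galectin Lgals7 (-3.34 ± 0.35), and Dmkn (-3.01 ± 0.20). Cav1 (-2.99 ± 0.22), Cyp26a1 (-2.97 ± 0.24), the small heat shock protein Cryab (-2.92) and Spink1 (-2.91) followed. Rcan1 fell as well (-1.32 ± 0.11, adjusted p = 2.35e-06), to 1441 ± 62.7. The rises were led by Hs6st2 (2.77 ± 0.15, adjusted p = 2.39e-08), Ms4a4d (2.67 ± 0.20), Chst15 (2.44 ± 0.30) and Pkdcc (2.18 ± 0.16), and included Cdkn1c (2.06), Zfhx3 (1.97) and Rgs5, a regulator of G protein signalling (1.85). In their other probe sets Chst15 was at 0.67 (adjusted p = 0.115) and Pkdcc at 1.05 (0.00457).

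Trophectoderm genes fell in this comparison, with 8 of 16 lower, 0 higher and 8 that did not pass (10 lower and 2 higher adjusted over the list alone). Their median was -0.55 (adjusted p = 1.9e-06, and 0.0799 with an estimated correlation), and Elf5 (-2.40 ± 0.25), Cited1 (-2.19 ± 0.32) and Krt19 (-1.57 ± 0.26) fell most. So did the endoderm list, with 4 of 13 lower, 0 higher and 9 that did not pass (7 lower and 1 higher adjusted over the list alone), among them Col4a1 (-1.75 ± 0.13) and Col4a2 (-1.29 ± 0.17). The median was -0.44 (adjusted p = 0.000231, and 0.259 with an estimated correlation). Primed epiblast genes rose, with 4 of 11 higher, 0 lower and 7 that did not pass (4 adjusted over the list alone), among them Dnmt3a (1.15 ± 0.20), Sall2 (1.00 ± 0.19) and Sox4 (0.86 ± 0.07). The median was 0.40 (adjusted p = 1.9e-06, and 0.14 with an estimated correlation). Neuroectoderm genes rose with them, with 5 of 11 higher, 1 lower and 5 that did not pass (5 and 1 adjusted over the list alone), among them Sox11 (0.90 ± 0.08) and Msi1 (0.88 ± 0.13). Their median was 0.27 (adjusted p = 0.000364, and 0.0568 with an estimated correlation). The 1 neuroectoderm gene that fell was Gbx2 (-0.85), a homeobox factor also present in naive stem cells, chosen after its value was seen. The calcineurin-NFAT list did not pass (median -0.02, adjusted p = 0.0948), although Rcan1 and, chosen after their values were seen, Ptgs2 (-2.66 ± 0.30), Egr2 (-1.37 ± 0.30) and Nr4a1 (-0.81 ± 0.11) were each lower. The cholesterol list passed (median -0.15, adjusted p = 0.0112, and 0.413 with an estimated correlation) with 0 of 15 genes called by limma (3 at an unadjusted p under 0.05, 2 lower adjusted over the list alone). It lost its call without CA-NFATc3 replicate 1 (0.0577) or replicate 2 with both (0.164). The fibroblast list did not pass (median 0.18, adjusted p = 0.386), although 2 of its 7 genes were called, Col1a2 (2.07, adjusted p = 0.000113) among them. At an unadjusted p under 0.05 in limma, 2 of the 7 were higher and 2 lower. In all, 711 genes differed, 283 higher and 428 lower, 192 of them by at least 2-fold (59 higher, 133 lower). The replicate block gave 1258 (534 higher, 724 lower), and leaving out CA-NFATc3 replicate 3 gave 385.

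Set against the label Foxd3 alone, both plasmids show what CA-NFATc3 adds on top of it. Few genes differed, and nearly all were higher. AU015836 (8.70-fold, 3.12 ± 0.17, adjusted p = 9.19e-08), Rgs5 (2.49 ± 0.20), and Col5a2 (2.44 ± 0.24) rose most. Bmp2 (2.25 ± 0.20), the myelin protein Pmp22 (2.18 ± 0.19), Capn6 (1.76, lost without the offset of 32, adjusted p = 0.0672) and Nptx1 (1.58) came after them. The 1 gene that fell was Tcf7l1, a repressor in the Wnt pathway (-0.53 ± 0.10, adjusted p = 0.0294). Tcf7l1 lost its call without Foxd3 replicate 2 or 3 or without any 1 replicate with both (adjusted p 0.0556 to 0.206). Rcan1 did not pass (0.45, adjusted p = 0.158), though it did with the replicate block (adjusted p = 0.0365). The counts were 38 genes by limma, 37 higher and 1 lower, 24 of the higher ones by at least 2-fold, and 96 with the replicate block (88 higher, 8 lower). All 18 arrays in 1 fit gave 63, and the count was 23 and 22 without Foxd3 replicates 1 and 2, and 25 and 23 without replicates 2 and 3 with both.

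Of the lists, fibroblast genes rose with both plasmids against Foxd3 (2 of 7 higher, 0 lower, 5 not passing; 3 adjusted over the list alone), by a median of 0.36 (adjusted p = 0.000272, and 0.0367 with an estimated correlation). The 2 were Col1a2 (1.76 ± 0.26, lost without the offset, adjusted p = 0.451) and Col3a1 (1.52 ± 0.22). The other 5 calls were small, and none held with an estimated correlation. Endoderm had a median of 0.13 (adjusted p = 0.0122, and 0.428 with an estimated correlation; 2 of 13 higher adjusted over the list alone) and trophectoderm one of 0.18 (0.0431, and 0.428 with an estimated correlation; 1 of 16). The interferon list was at 0.20 (0.0359, and 0.154 with an estimated correlation; 1 of 6, Cxcl10, higher). Neuroectoderm was at -0.12 (0.0359, and 0.154 with an estimated correlation; 0 of 11) and pluripotency at -0.05 (0.0403, and 0.451 with an estimated correlation; 0 of 25). Apart from Cxcl10 (1.31 ± 0.23, adjusted p = 0.0157; 0.0879 without Foxd3 replicate 1, 0.0816 without Foxd3 replicate 3, 0.0768 without the offset), 0 of their genes were called by limma over all genes; at an unadjusted p under 0.05 there were 5 in endoderm, 2 in trophectoderm, 1 in neuroectoderm and 1 in pluripotency. The block ended the trophectoderm call (adjusted p = 0.0572), and no filter (0.0971 to 0.291) or all 18 arrays in 1 fit (0.129 to 0.181) ended all 5. Without 1 array, the calls ended for endoderm (replicate 3 with both, 0.107), trophectoderm (Foxd3 replicate 3 or any replicate with both, up to 0.358) and interferon (Foxd3 replicate 2 or any replicate with both, up to 0.422). They also ended for neuroectoderm (replicates 2 and 3 of either group, up to 0.137) and pluripotency (Foxd3 replicate 1, or replicates 1 and 2 with both, up to 0.287).

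**Figure D3:**
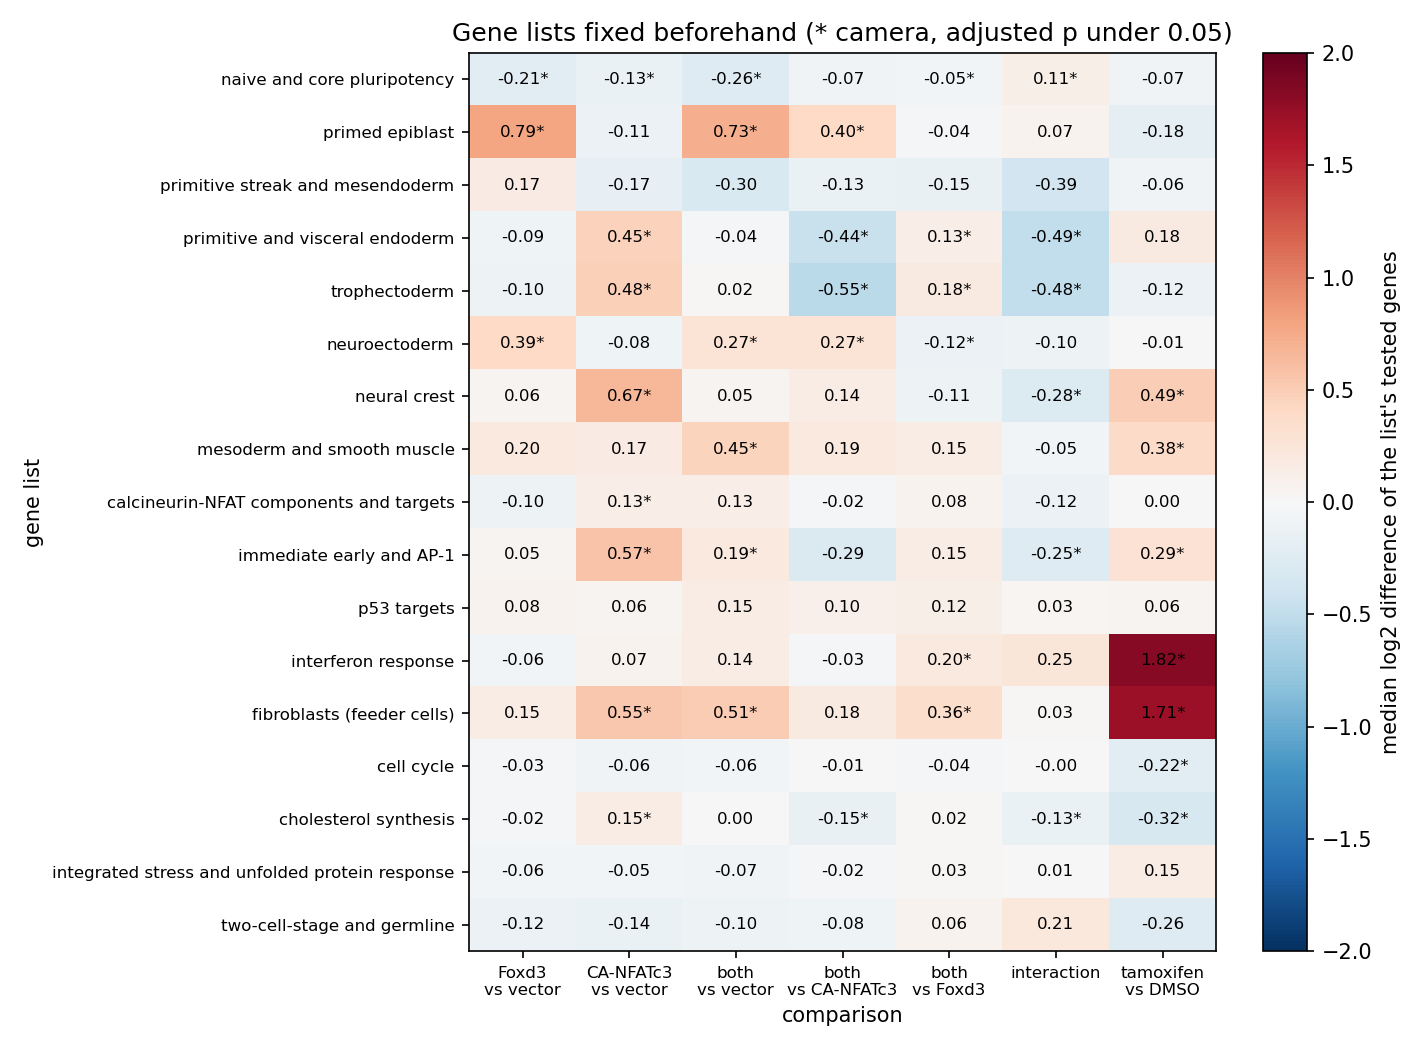
Median log2 difference of the tested genes of each of 17 gene lists (vertical axis) in the 7 comparisons (horizontal axis), printed and coloured in each cell, with a star where camera called the list. Trophectoderm is at 0.48 for CA-NFATc3 against vector and at -0.55 for both against CA-NFATc3, and primed epiblast at 0.79 for Foxd3 against vector.

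Whether the change with the label Foxd3 differed with and without CA-NFATc3 was tested as an interaction, the difference of the changes in the presence and absence of CA-NFATc3. It was negative for genes that CA-NFATc3 alone had raised: S100g (-5.76 ± 0.27, adjusted p = 1.23e-08), Gsn (-4.26 ± 0.27, adjusted p = 5.05e-07), Lgals7 (-3.69 ± 0.49) and Dmkn (-3.23 ± 0.28). The same held for Cyp26a1 (-2.90 ± 0.34, lost without the offset, adjusted p = 0.304), Rcan1 (-1.14, adjusted p = 0.0013) and Col4a1 (-2.46 ± 0.19, adjusted p = 3.48e-06). Zap70 (2.53 ± 0.40, adjusted p = 0.00421) and Rgs5 (2.17 ± 0.28, adjusted p = 0.00104) had the largest positive terms. For Zap70 this rests on 1 of 3 probe sets, the others being at 0.48 (adjusted p = 0.836) and 0.80 (0.549), and the mean of its probe sets gave 1.27 (0.0168). Limma called 94 genes, 10 positive and 84 negative, 74 of them at 2-fold or more (4 positive, 70 negative); the replicate block gave 245 (61 positive, 184 negative), all 18 arrays in 1 fit 161 and array weights 172. The count was 60 without Foxd3 replicate 3 and 48 without CA-NFATc3 replicate 3. Of the 536 genes higher with CA-NFATc3 alone, 253 were called lower with both than with CA-NFATc3, against 19.8 in chance overlap of the 2 sets of calls. Since these contrasts share the CA-NFATc3 arrays, some opposite movement comes from the design: simulated data without any effect gave correlations of -0.526 to -0.478 between them, against the observed -0.636. The interaction was called negative for 84 of the 536. Their selection favours this count, since the interaction holds the same CA-NFATc3 and vector arrays with the opposite sign. Of the 536, 31 were called higher with both than with Foxd3, a comparison that shares no array with CA-NFATc3 against vector. The median change of the 536 genes was 0.83 for CA-NFATc3 against vector, a value raised by the selection of these genes in that comparison, and 0.21 for both against Foxd3. To remove the selection, a step chosen after these values were seen, genes were selected without replicate 1, 2 or 3 of CA-NFATc3 and vector and read in the replicate left out. The medians of the 434, 362 and 234 genes higher were then 0.78, 0.89 and, for the last, above both, against 0.22, 0.25 and 0.33 for both against Foxd3.

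The trophectoderm list had a median interaction term of -0.48 (adjusted p = 4.24e-05, and 0.236 with an estimated correlation), with 3 of 16 genes negative, 0 positive and 13 that did not pass (5 negative adjusted over the list alone): Cited1 (-2.62 ± 0.45), Elf5 (-2.10 ± 0.35) and Eomes, a T-box factor of trophoblast and mesendoderm (-1.59 ± 0.28). For endoderm it was -0.49 (adjusted p = 0.000212, and 0.236 with an estimated correlation), with 2 of 13 negative (2 adjusted over the list alone), Col4a1 and Col4a2 (-1.69 ± 0.24). Without the offset of 32, Cited1 (adjusted p = 0.129) and Elf5 (0.447) lost their call. The immediate early list was negative too (median -0.25, adjusted p = 0.00609, and 0.236 with an estimated correlation; 2 of 15, 3 adjusted over the list alone), with Ccn1 at -1.94 ± 0.28 (not called with the mean of its probe sets, adjusted p = 0.139). Pluripotency genes had positive terms as a list (median 0.11, adjusted p = 0.000371, and 0.236 with an estimated correlation), with 0 of 25 genes called by limma (4 at an unadjusted p under 0.05, 3 adjusted over the list alone). The cholesterol synthesis (median -0.13, adjusted p = 0.0265, and 0.606 with an estimated correlation; 0 of 15 in limma, 3 at an unadjusted p under 0.05) and neural crest (median -0.28, adjusted p = 0.047, and 0.236 with an estimated correlation; 1 of 5, 2 adjusted over the list alone) lists passed as well. Both calls ended without vector replicate 2, Foxd3 replicate 1, CA-NFATc3 replicate 1 or replicate 2 with both, and neural crest also without replicate 3 with both (adjusted p up to 0.38 and 0.146). Neural crest further lost its call with the replicate block (0.0977) and turned to a median of 0.05 with a filter on the mean.

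**Figure D4:**
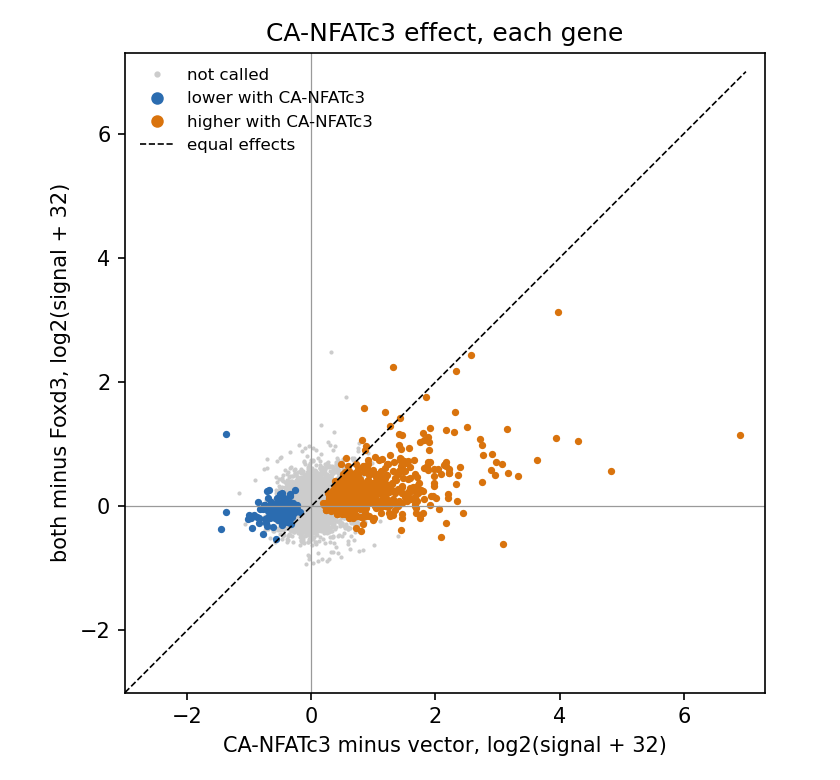
Each point is 1 gene, with its log2 difference for CA-NFATc3 minus vector on the horizontal axis and for both minus Foxd3 on the vertical axis, coloured where CA-NFATc3 alone had a called effect; the dashed line marks equal effects. The slope over the called genes, which were selected on the horizontal axis, is 0.238, and the 536 genes higher with CA-NFATc3 have medians of 0.83 and 0.21.

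Comparisons that share no array were set side by side across genes, which are not independent replicates, so no p is given; 4 such relations were computed. The change with the label Foxd3 in the absence and presence of CA-NFATc3 correlated at r = 0.376 (jackknife SE over 12 arrays 0.0695, Spearman's rho 0.333). Of the 334 genes called without CA-NFATc3, 302 had the same sign with it. Of them 115 were called higher in both comparisons, against 4.83 in chance overlap, and 49 lower, against 5.01. The change with CA-NFATc3 in the absence and presence of Foxd3 correlated at r = 0.366 (jackknife SE 0.0905, rho 0.245), with 562 of 680 genes of the same sign. Over the genes called without the other plasmid the slope was 0.650 for the label Foxd3 and 0.238 for CA-NFATc3, and selecting genes on the first comparison lowers both slopes.

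The conditional knockout cells with tamoxifen were compared with those with DMSO for the effect of deleting Foxd3, from which an effect of tamoxifen itself cannot be separated. Foxd3 fell at least 3.33-fold (-2.08 ± 0.27, adjusted p = 0.000146, and -3.24 without the offset), with all 3 tamoxifen arrays under 65.8. Genes of the interferon response and of fibroblasts were among the largest rises. Usp18, an interferon-induced protease that removes ISG15, went from a signal of 166 to 3000 (15.3-fold, 3.93 ± 0.08, adjusted p = 1.22e-10), and Ifit1 (3.84 ± 0.15), Rtp4 (3.66 ± 0.19) and Ifit3 (3.55 ± 0.14) rose with it. The metalloproteinase Mmp3, which fibroblasts make, went from 237 to 3601 (13.6-fold, 3.76 ± 0.12, adjusted p = 1.83e-09), and the chemokine Ccl2 rose by 3.40 ± 0.10. The matrix proteins decorin (Dcn, 3.54 ± 0.18) and periostin (Postn, 3.49 ± 0.10) went from 225 to 2863 and from 255 to 3172. Besides Foxd3, the largest falls were in Gpx2, a glutathione peroxidase (-2.09 ± 0.24, adjusted p = 5.88e-05), Ppp1r3c (-1.85 ± 0.23), 1700097N02Rik (-1.74 ± 0.08), and A2m (-1.54 ± 0.13). Fgf4, a growth factor made by pluripotent cells, fell from 2779 to 967 (-1.50 ± 0.11, adjusted p = 9.9e-07), and G2e3 (-1.49) and Prmt8 (-1.46) fell to a like extent.

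With tamoxifen, 13 of 14 interferon genes were higher, 0 lower and 1 did not pass (13 adjusted over the list alone; median 1.82, camera adjusted p = 2.83e-14, and 0.0252 with an estimated correlation). Likewise 13 of 14 fibroblast genes were higher, 0 lower and 1 did not pass (13 adjusted over the list alone; median 1.71, adjusted p = 5.77e-13, and 0.0964 with an estimated correlation), Col1a2 among them (2.72 ± 0.08). The actin 3'/5' ratio also differed, 1.89 ± 0.00311 with tamoxifen and 2.15 ± 0.0884 with DMSO (SD, n = 3). The arrays did not overlap, as happens by chance in 2 of the 20 orders of 3 and 3 arrays. The same ratio of Gapdh showed no such difference, at 1.015 ± 0.0144 with tamoxifen and 1.013 ± 0.0309 with DMSO, with overlapping arrays.

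Cell cycle genes fell with tamoxifen, in the arrays in which fibroblast genes rose by a median of 1.71: 11 of 17 were lower, 1 higher and 5 did not pass (12 and 1 adjusted over the list alone). Their median was -0.22 (adjusted p = 0.000225, and 0.339 with an estimated correlation). The mitotic kinases Plk1 (-0.58 ± 0.07) and Cdk1 (-0.42 ± 0.05) and the cyclin Ccna2 (-0.37 ± 0.05, and -0.02 in its other probe set) fell most, and the 1 that rose was Ccnd1, a cyclin of G1 (0.64), chosen after its value was seen. Cholesterol synthesis genes fell in the same arrays, with 10 of 15 lower, 1 higher and 4 that did not pass (10 and 1 adjusted over the list alone), led by Dhcr7 (-0.76 ± 0.13), Insig1 (-0.67 ± 0.10) and Stard4 (-0.59 ± 0.08). The median was -0.32 (adjusted p = 0.000225, and 0.339 with an estimated correlation), and the 1 that rose was Ebp, a sterol isomerase (0.43), also chosen after its value was seen.

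Mesoderm and smooth muscle genes rose alongside the interferon and fibroblast lists, with 8 of 15 higher, 1 lower and 6 that did not pass (8 and 1 adjusted over the list alone). The median was 0.38 (adjusted p = 0.0111, and 0.537 with an estimated correlation), and Myl9 (1.27 ± 0.17), smooth muscle actin Acta2 (1.27 ± 0.11) and Actg2 (0.86 ± 0.16) rose most. Immediate early genes rose too, with 11 of 18 higher, 2 lower and 5 that did not pass (11 and 2 adjusted over the list alone) and a median of 0.29 (adjusted p = 0.0154, and 0.537 with an estimated correlation); Fosl2 was at 2.03 ± 0.14, although its other probe set had the opposite sign (-0.40, adjusted p = 0.129) and the mean of its probe sets rose less (0.81, adjusted p = 0.00147). In the neural crest list 3 of 6 were higher, 0 lower and 3 did not pass (4 adjusted over the list alone): Snai2 (1.69 ± 0.10), Ets1 (0.75 ± 0.14) and Erbb3 (0.31 ± 0.07). Other probe sets of Ets1 were at 0.15, 0.33 and 0.79, of which only the last was called. This list's median was 0.49 (adjusted p = 0.0154, and 0.295 with an estimated correlation). Without DMSO replicate 1 the calls of neural crest (adjusted p = 0.0566), mesoderm (0.0536) and immediate early genes (0.0698) ended; neural crest also ended with no filter (0.234) and immediate early genes with all 18 arrays in 1 fit (0.0969).

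Pluripotency genes moved both ways with tamoxifen and did not pass as a list (5 of 25 higher, 7 lower, 13 not passing; 5 and 8 adjusted over the list alone; median -0.07, adjusted p = 0.309). Sox2 fell by 0.17 on the log2 scale (adjusted p = 0.00971, and 0.0841 without a variance trend) and Nanog did not pass (-0.12, adjusted p = 0.103, and 0.0207 with each array centred on its median). Pou5f1 was lower (-0.19 ± 0.06, adjusted p = 0.0186), a call that ended with quantile normalization (0.104), without a variance trend (0.0997), with all 18 arrays in 1 fit (0.0561), without DMSO replicate 2 (0.0854) and without tamoxifen replicate 1 (0.0583) or 2 (0.078). Primed epiblast genes did not pass as a list (2 of 13 higher, 6 lower; median -0.18, adjusted p = 0.28), although Fgf5, a marker of that state, rose (0.85, adjusted p = 0.00285). The remaining lists did not pass either: endoderm (5 of 14 higher, 1 lower; median 0.18, adjusted p = 0.0995), trophectoderm (1 of 16 higher, 4 lower; -0.12, 0.489), neuroectoderm (2 of 12 higher, 3 lower; -0.01, 0.657) and calcineurin-NFAT (4 of 20 higher, 3 lower; 0.00, 0.657). Cdx2, a trophectoderm factor, was at 0.02 (adjusted p = 0.939). Of the calcineurin-NFAT genes, Rcan1 rose (0.51, adjusted p = 0.000268) and Nfatc4 fell (-0.58, adjusted p = 0.000525), the latter not with the mean of its probe sets (-0.20, adjusted p = 0.21).

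Camera called 4 of the lists in none of the 7 comparisons. With tamoxifen, p53 targets (5 of 14 higher, 1 lower) had a median of 0.06 (adjusted p = 0.187), and stress response genes (5 of 15 higher, 5 lower) one of 0.15 (0.906). For germline genes, with those of the 2-cell stage (3 of 12 higher, 5 lower), it was -0.26 (0.187), and for primitive streak genes (1 of 5 higher, 0 lower) -0.06 (0.906). Limma called 4165 of 12093 genes between tamoxifen and DMSO (34.4%), 2122 higher and 2043 lower, 501 of them by at least 2-fold (458 higher, 43 lower). All probe sets tested by themselves gave 6328 calls. Centring each array on its median, which removes a shift of 0.07 between the groups, changed the split to 1704 higher and 2924 lower, and the directions of small changes depend on that shift. The replicate block gave 4027.

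**Figure D5:**
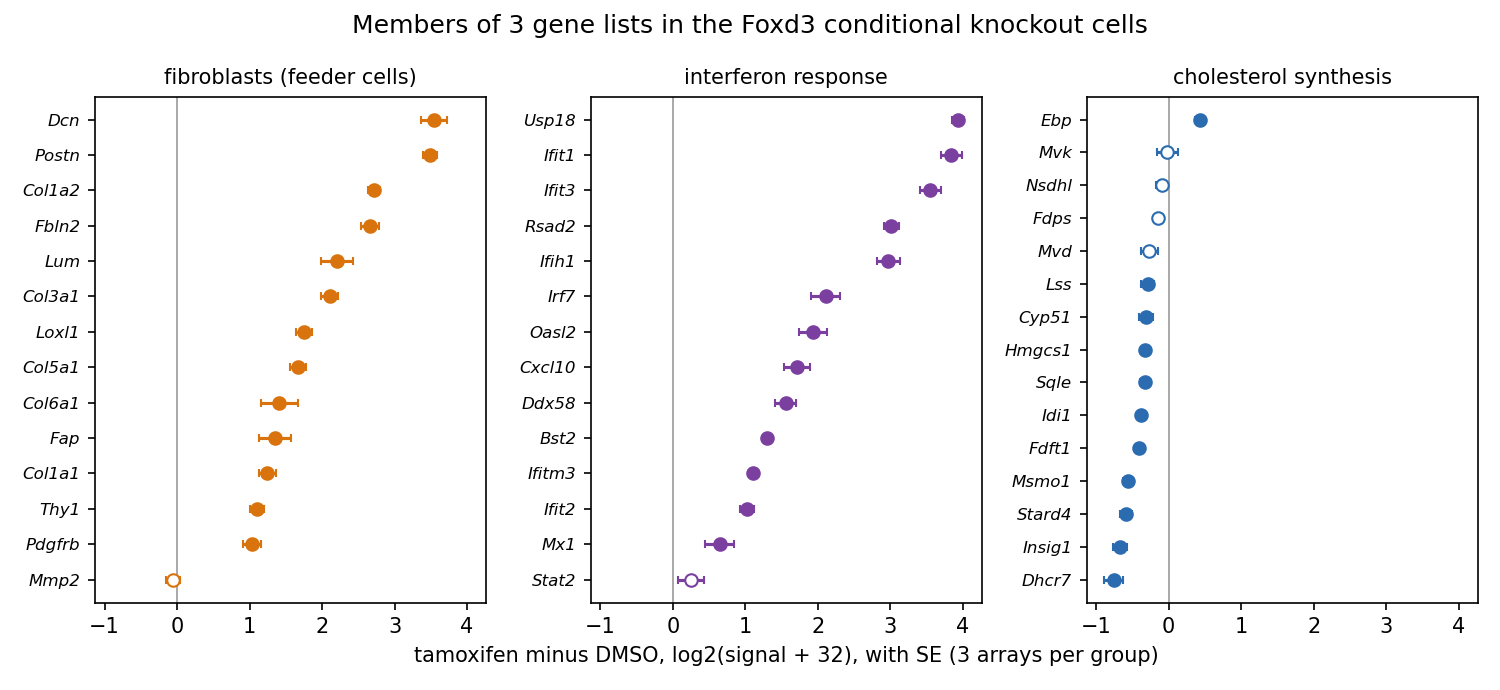
Log2 difference, with SE, of each tested member of the fibroblast, interferon and cholesterol synthesis lists for tamoxifen minus DMSO, 3 arrays per group, with open circles for genes that did not pass. The list medians are 1.71, 1.82 and -0.32.

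Gain and loss of Foxd3 by label were compared across 11223 genes. The change with the label Foxd3 and that with tamoxifen correlated at r = 0.0209 (jackknife SE 0.0644, rho -0.006). The sign turned without vector replicate 2 (r = -0.0124) or Foxd3 replicate 3 (-0.0162). Of 324 genes called with the label Foxd3 and tested here, 134 had the same sign with tamoxifen. In detail, 49 genes rose in both (29.9 in chance overlap), 59 rose with the label Foxd3 and fell with tamoxifen (34.3), 39 fell and rose (20.8) and 22 fell in both (23.9). CA-NFATc3 against vector and tamoxifen against DMSO correlated at r = 0.218 (jackknife SE 0.0684, rho 0.145). Here 205 genes were higher in both (78.7 in chance overlap), 55 lower in both (25.1) and 51 higher with CA-NFATc3 and lower with tamoxifen (90.3). The genes higher with tamoxifen include fibroblast genes whose source stays open, and some of these, such as Cav1 and Col5a2, also rose with CA-NFATc3. How much of the overlap they make up was not tested.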

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

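Of the tests below, those of a fibroblast population with an unchanged profile, of an exchange of only 1 pair of groups, and of an equal loss for every gene were chosen only after the result was seen.

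A difference between groups marked the interaction: the change with the label Foxd3 differed with and without CA-NFATc3 for 94 genes by a direct test of that difference. The largest terms were those of S100g (-5.761), Gsn (-4.257), Lgals7 (-3.687), Dmkn (-3.232) and Cyp26a1 (-2.897), and on the positive side those of Zap70 (2.528, and 1.271 with the mean of its probe sets), Rgs5 (2.175), Stra8 (1.289), AW551984 (1.28) and Lefty1 (0.6968). Stra8 lost its call without vector replicate 2 or 3, Foxd3 replicate 1 or replicate 3 with both (adjusted p up to 0.0694). AW551984 lost it without vector replicate 3, Foxd3 replicate 3 or replicates 2 or 3 with both (up to 0.0731). Lefty1 lost it without any of 9 of the 12 arrays (up to 0.117), the exceptions being vector replicate 1, Foxd3 replicate 1 and replicate 2 with both. Median interaction terms of called lists were -0.4901 for endoderm, -0.4849 for trophectoderm, -0.2786 for neural crest, -0.2536 for immediate early genes, -0.1341 for cholesterol synthesis and 0.1117 for pluripotency. None of these calls held with an estimated inter-gene correlation. That of neural crest also ended with the replicate block (camera adjusted p = 0.0977).

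Probe sets that the annotation gives no single gene were left out of the comparisons and also carried signal that differed between groups. In limma, 24 of 2985 such probe sets were called for Foxd3 against vector, 31 for CA-NFATc3 against vector, 34 for both against vector, 39 for both against CA-NFATc3 and 4 for both against Foxd3, and 609 of 3230 for tamoxifen against DMSO.

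The smaller CA-NFATc3 effect in the arrays labelled with both was weighed first. An equal loss for every gene, as less plasmid with a linear response might give, was tested on relative rises, each over its own group without CA-NFATc3. Of 208 genes raised at least 2-fold by CA-NFATc3, 11.06% (exact 95% interval 7.14 to 16.1%) kept a share that differed from the median share by more than 3 SE, where under 5% was needed. The median share was 13.5%, itself lowered by selecting on that rise. In these 23 genes the share was higher in 14, such as AU015836, Bmp2, Pmp22 and Col5a2, and lower in 9, such as S100g, Gsn and Efnb2. This does not decide on less plasmid, since a gene that the label Foxd3 itself moves can depart through its changed baseline. Efnb2, for example, was at log2 3.16 for Foxd3 against vector. Less CA-NFATc3 transcript stays open, since the lower of the Nfatc3 probe set changes was -0.1149 (adjusted p = 0.801) and the probe sets did not show the plasmid even with CA-NFATc3 alone. A lower dose of plasmid, acting with the same or a different curve for each gene, stays open, since the plasmid dose was not measured. So does an action of Foxd3 on NFATc3 responses, the biological explanation that the design names.

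The lower Foxd3 signal in the arrays labelled Foxd3 was weighed next. An exchange of labels in only 1 of the pairs (vector with Foxd3, or CA-NFATc3 with both) would leave the lower signal of the other pair unexplained. The changes without and with CA-NFATc3, which share no array, also went the same way across genes (r = 0.3759). Such an exchange needs a negative value there, provided that Foxd3 acts the same way with and without CA-NFATc3. An exchange in both pairs stays open. The genes called for Foxd3 against vector correlated with tamoxifen against DMSO at r = -0.01576 (-0.0395 to 0.0357 without any 1 array). This lies between the bounds of 0.1 and -0.1 set before the test. A value beyond them would not by itself have decided, since an effect of tamoxifen cannot be separated and fibroblast genes rose in that comparison. A probe set that reads only the cell's own transcript, reduced where Foxd3 is overexpressed, is a biological explanation that was not tested, since the position of the probe set is not known here.

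Fibroblast genes that rose with tamoxifen were weighed last: of 28 further genes abundant in fibroblasts, fixed before the test, 25 of the 27 measured, 92.59%, were called higher, with a median of 1.38. A larger share of fibroblast-like cells, such as feeder cells, may be the source. The further and the listed fibroblast genes together, 41 genes, were already higher in the DMSO than in the vector arrays. Their median log2 difference was 1.543 (100th percentile of 10000 random lists of like mean). Of the listed genes, decorin (Dcn) was at 9.85 with vector, 225 with DMSO and 2863 with tamoxifen, and Col1a2 at 27.2, 1130 and 7594. The DMSO and vector arrays differ in cells and experiment, so culture and batch cannot be told apart in this difference. The percentile compares gene lists and does not measure the spread between experiments. Scaling between arrays is argued against (the list's median kept 0.9596 of its value). For a larger share of 1 fibroblast population with an unchanged profile and nothing else, equal changes were looked for. Of 18 genes, 61.11% (exact 95% interval 35.7 to 82.7%) departed from their median of 2.36 by more than 3 SE, from 0.95 for Col6a2 to 3.54 for Dcn. This cannot decide, since the offset and the signal of other cells were not subtracted. Both lower the change of genes dim with DMSO, such as Col6a2 (59.1 with vector, 123 with DMSO). Genes bright with DMSO still differed, with Col1a2 (1130) at 2.72 and Cav1 (767) at 1.98. A larger share with an unchanged or an altered profile, and a rise within the stem cells after loss of Foxd3 or with tamoxifen itself, stay open.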

How the results depend on the processing

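Of 252 results of named genes, under the alternatives run for genes (all but at least 2-fold), 4658 values kept their side of the threshold, 180 lost the call, 9 gained it and 0 reversed with a call. Of the 4658, 83 were values without a call that changed sign. For the 41 called lists, before the estimated inter-gene correlation given below, 730 kept, 78 lost the call and 1 reversed. Foxd3 against vector kept 16 of 24 called named genes and 3 of 3 lists under each of these alternatives, CA-NFATc3 against vector 27 of 31 and 4 of 8, both against vector 26 of 33 and 3 of 6, and both against CA-NFATc3 28 of 30 and 4 of 5. Likewise kept were, for both against Foxd3, 7 of 11 and 1 of 6, for the interaction 10 of 19 and 4 of 6, and for tamoxifen against DMSO 33 of 37 and 4 of 7. Where no cause is given below, the cause was not tested. In that order of contrasts, the replicate block gave 783, 1104, 1122, 1258, 96 and 245 genes (and 4027 with tamoxifen, within 1.5 times), and every gene called without the block in the transfected cells stayed called. The block ended 3 of the 41 list calls, gave 8 called lists for both against Foxd3 (6 otherwise, 1 of them lost) and 6 for both against CA-NFATc3 (5), and among named genes added the calls of Nfatc3, Nanog and Rcan1. At least 2-fold gave 66, 213, 119, 192, 24 and, with tamoxifen, 501 genes by construction, as it only removes calls. Array weights gave 552 for Foxd3 against vector and 172 for the interaction. All 18 arrays in 1 fit gave 63 for both against Foxd3 and 161 for the interaction, and 6328 probe sets were called with tamoxifen when each was tested by itself, more being tested. Leaving out 1 array, the counts lay between 158 and 282 for Foxd3 against vector, 349 and 620 for CA-NFATc3 against vector, 322 and 461 for both against vector, 385 and 585 for both against CA-NFATc3, 22 and 28 for both against Foxd3, and 48 and 104 for the interaction, with fewer samples in each fit. Called lists, with all probe sets, were 8 for Foxd3 against vector (3 otherwise), 11 for both against vector (6), 9 for both against CA-NFATc3 (5) and 11 with tamoxifen (7). No filter gave 8 for both against CA-NFATc3 and 1 for both against Foxd3 (6 otherwise), which had 2 with the mean of the probe sets, 1 with all 18 arrays in 1 fit and 2 to 6 without 1 array; tamoxifen had 4 to 8. An estimated inter-gene correlation left 0 for CA-NFATc3 against vector, 2 for both against vector, 0 for both against CA-NFATc3, 1 for both against Foxd3, 0 for the interaction and 1 with tamoxifen. The neural crest list of the interaction reversed to 0.05058 with a filter on the mean. The correlation of the Foxd3 changes without and with CA-NFATc3 was 0.2624 with no filter and 0.5688 over genes called in either; that of the CA-NFATc3 changes was 0.2286 and 0.5411, and 0.2445 by Spearman. Foxd3 against vector with tamoxifen reversed to -0.006138 by Spearman and ranged from -0.01624 to 0.04798 without 1 array, and CA-NFATc3 with tamoxifen was 0.1449 by Spearman. Signal over background limits the results for genes near the floor: S100g at 1.55 with vector, Cav1 and Cyp26a1 with vector and Foxd3 with tamoxifen have log2 changes set in part by the offset, and Cdx2 and Fgf5 could not be tested in the transfected cells.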

Other observations

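The test of an equal loss for every gene, the groupings within replicate numbers and the genes named in the next paragraph were chosen only after the values were seen; the other splits of the arrays were planned.

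Within lists that did not pass as a whole, single genes moved with tamoxifen. Tfap2c, a factor of trophectoderm and germ cells, rose by 1.22 ± 0.08 (adjusted p = 4.32e-07), while Ascl2 (-1.28 ± 0.36, adjusted p = 0.0177) and Krt19 (-0.90 ± 0.19) fell. Pdgfra, a receptor of primitive endoderm and of fibroblasts, rose by 1.33 ± 0.14 and Dab2 by 1.02 ± 0.12. Of naive genes, Tbx3 (0.79 ± 0.10) and Dppa2 (0.49 ± 0.11) rose, and Tdgf1, a coreceptor of Nodal (-0.49 ± 0.04), and Lin28a (-0.58 ± 0.07) fell. Of primed epiblast genes, Dnmt3a fell (-0.78 ± 0.11) and Wnt8a rose (0.82 ± 0.18). The p53 targets Fas (1.12 ± 0.23) and Cdkn1a, the inhibitor p21 (0.68 ± 0.06), rose and Bbc3, the proapoptotic Puma, fell (-0.56 ± 0.12). Zfp352, a gene of the 2-cell stage, rose (1.89 ± 0.17), and the germline genes Mael (-0.93 ± 0.11) and Stra8 (-0.81 ± 0.14) fell. The NFAT targets Ptgs2 (2.14 ± 0.10, adjusted p = 3.65e-08) and Csf2 (1.65 ± 0.22) rose, beside the fibroblast list's median of 1.71.

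Some genes answered CA-NFATc3 as much or more in the arrays labelled with both. Bmp2 had a log2 change of 1.32 for CA-NFATc3 against vector and 2.25 ± 0.20 for both against Foxd3, Rgs5 0.32 (adjusted p = 0.501) and 2.49 ± 0.20, and Col5a2 2.58 and 2.44 ± 0.24. The interaction was called for Rgs5 (2.17 ± 0.28, adjusted p = 0.00104) and not for Bmp2 (0.93, adjusted p = 0.21) or Col5a2 (-0.14, adjusted p = 0.974); Zap70, lower with CA-NFATc3 than with vector, had a positive interaction term of 2.53 ± 0.40 (1.27 with the mean of its probe sets). Bmp2, Rgs5 and Col5a2 were among the largest rises of both against Foxd3, so a change kept there follows from their choice. Bmp2 and Col5a2 are also among the genes with a higher share in the test above. They therefore add no separate evidence on an equal loss for every gene.

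Other splits of the arrays into 3 and 3 were counted, with only the 2 groups of each comparison in the fit. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In each comparison only 1 of the 10, the real split itself, gave as many genes. The real and highest other counts were 314 and 0 for Foxd3 against vector, 574 and 0 for CA-NFATc3 against vector, 492 and 1 for both against vector, 574 and 0 for both against CA-NFATc3, 27 and 1 for both against Foxd3, and 4165 and 0 for tamoxifen against DMSO. Among splits that part all pairs of equal replicate number, the highest other count was 0 in each. For the interaction, 2 of 100 groupings of the 12 arrays gave at least the real 94 genes, the real one included. The highest other, 136, came from a grouping that keeps all 3 CA-NFATc3 arrays together, and the next highest was 5. Of 100 groupings that put 1 array of each replicate number in each group, 4 gave at least 94, the real one included. The highest other, 537, was several times the real count. With the main effects of both plasmids removed first, the highest other was 1 against 82 for the real grouping, so the high counts came with those main effects. Real changes also enter the spread of mixed groups and lower most other counts, and none of these counts is taken to exclude chance.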
